A study of Caenorhabditis elegans with 2 samples.

How the data were processed

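The samples were 2 biological replicates of L2 larvae of the C. elegans strain OP86, which carries the unc-119(ed3) mutation and the integrated transgene wgIs86, with the protein PEB-1 as the target of the immunoprecipitation. Both were assigned to 1 group from their labels, and the replicate numbers are those of the labels. A control experiment is listed in the labels only as a possible control, and it was not analysed here. The extraction protocol is not provided, per the labels, and the fragment size range is 150 to 350 bp.

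The deposited files used were peak lists for the builds ce10 and ce11: per build 1 relaxed list for each replicate, 1 for both replicates pooled, and 1 thresholded list for the series. Per their names and the accompanying file listing, the relaxed lists hold peaks and background meant as input for the irreproducible discovery rate (IDR) procedure. That procedure compares the ranks of peaks between lists, and the thresholded list is the optimal IDR set. Which lists were compared to set its size is not given in the sources used here. Of its 160 ce11 peaks, 56 ranked within the highest 160 of replicate 2 and 11 overlapped no peak there. A place in the thresholded list was therefore not taken as recurrence in both replicates. Replicates were called separately and also pooled, per the accompanying file listing, each with a control file. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The signal of each peak is the peak height as deposited by the authors, on a scale that was not given in the sources used here, and it was used only to rank, describe and filter peaks within a list. The last column but 1 of each list is, by the file format, a −log10 q-value as deposited, between 1.18 and 2.23 for the ce11 thresholded peaks. In the deposited pooled lists the same column holds values below 0 for 29058 of the 30000 ce11 peaks, from -0.0944 to 2.23, which a −log10 q-value cannot take, so it was treated as a score and used only to break ties of rank. The thresholded peaks carry the deposited values of the pooled list in this column, so for them too it was not taken as a measure of significance. The 160 thresholded ce11 peaks were checked to be the 160 highest-ranked peaks of the pooled list. Leaving out reads by depth, duplicates or mapping quality could not be varied, since the peaks were the starting point. Signal tracks and alignments were not used here.

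Peak height depends on read depth and on the copy number of a region, and a control from a strain without the same transgene does not remove extra copies; the genome of the control strain is not given in the sources used here. Relaxed lists were all 30000 peaks long, so their lengths carry no information on the number of bound sites.

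All positions are ce11, 1-based, which is the assembly WBcel235. Genes came from Ensembl release 115 of that assembly (46890 genes, 19973 of them protein-coding, 44762 that are not pseudogenes), with symbols for 3362 genes filled in from RefSeq. Where annotations overlapped, a summit was classed as coding exon first, then 5′ UTR, 3′ UTR, exon of a non-coding RNA gene, intron of a protein-coding gene and intergenic. A target was a gene that is not a pseudogene with a thresholded summit from 1000 bp upstream to 200 bp downstream of an annotated TSS.

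Overlap of peaks meant at least 1 bp. Promoter and location shares were compared with 10000 random placements of the peaks on their own chromosomes, replicate overlap with 1000 placements, the chromosome counts with 100000 multinomial draws, and the transgene loci with 10000 random windows. Motif and k-mer shares used presence on either strand within 100 bp of the summit, with Fisher's exact test against flanks centred 500 bp away or against 29815 pooled peaks that overlap no thresholded peak. The tests against flanks do not use the pairing of each summit with its own flanks, and flanks of neighbouring peaks can reach another peak. GC-matched backgrounds took up to 10 such peaks per thresholded peak in GC bins of 2 percentage points, 1522 windows in all. YDTGCCRW (in IUPAC letters) is the consensus recalled from published binding work on PEB-1. Gene lists were tested with Fisher's exact test and Benjamini-Hochberg adjustment over the 39 lists, named lists against protein-coding genes and lists by gene class against all genes that are not pseudogenes; 3 listed symbols had no match. Leaving out a replicate meant using the 160 highest-ranked peaks of the other replicate's list in place of the thresholded set. The threshold for calls was 0.05 and intervals are exact 95% binomial (Clopper-Pearson) or, for odds ratios, normal on the log scale. No test across replicates was possible with 1 group, so p-values describe peaks and genes of this experiment.

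The tests, gene lists, motifs and main alternatives were fixed before the data were examined. The genes named were the gene with the nearest TSS for each of the 20 strongest ce11 peaks, at most 4 targets of each list in order of signal, and always peb-1, unc-119, flh-1, flh-2, flh-3, myo-2, ceh-22, pha-4, lin-4 and let-7. Alternatives covered the peak set, the build, the overlap rule, the promoter window, the genes counted, the sequence window and background, k, and the flank of the transgene loci. Exclusion of the peaks within 20 kb of peb-1, the subset in the highest 1000 of both replicates, the nearest protein-coding TSS, the smaller random backgrounds for 6-mers (20 draws), the other-pooled and GC-matched backgrounds for non-coding RNA exons, and the alternatives for GAGAGA, DTGCCR and heterochronic microRNAs were chosen after seeing the data.

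Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The procedures were tested on simulated data. With no planted sequence 0 6-mers were called, and a planted 6-mer ranked 1. Of 100 random peak sets 5 were called for the promoter share, and peaks planted in promoters gave p = 0.0002 in the permutation test by placement. In 100 random target sets of 195 genes there were 2 list calls over all 39 lists, and planting 10 ribosomal protein genes called 1 list. With 45 shared peaks planted, 45 were found. The simulated genes, positions and windows were drawn independently at random. These checks therefore do not give the error rate for genes that share peaks or for summits richer in GC than their background.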

Results

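DNA bound by a green fluorescent protein (eGFP) fusion of PEB-1 was mapped in second-stage (L2) larvae of the nematode Caenorhabditis elegans. PEB-1 is a DNA-binding protein with a FLYWCH zinc finger, known for binding an enhancer of myo-2, the myosin heavy chain gene of pharyngeal muscle. The assay was ChIP-seq, in which chromatin carrying the tagged protein is pulled down and its DNA is sequenced. There was 1 group of 2 biological replicates, each of whole animals of mixed sex, and no comparison group. The question the design allows is therefore where the tagged protein was found in the genome. The deposited thresholded list held 160 peaks in coordinates of the ce11 build, each 356 bp wide, covering 0.0570 Mb. Signal, the peak height as the authors' peak caller gave it, ranged from 35.4 to 202 with a median of 43.7, and is used here only to rank peaks within a list. Read depth was not given in the sources used here, so the 95% exact binomial (Clopper-Pearson) intervals of shares cover counting error over peaks only.

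The strongest peaks lay at peb-1 itself, in the introns of lin-42 and pqn-41, and upstream of bet-2 and egl-26. The 4 highest of all 160 peaks fell in or beside peb-1 (X:2211051-2218988, plus strand), with signals of 202, 188, 165 and 122. Each of those summits lay in an exon of an annotated short non-coding RNA gene (T14F9.17, T14F9.14, T14F9.11 and T14F9.20), and 3 of the 4 summits were inside the peb-1 gene body. The peak of lin-42, which encodes a homologue of the circadian protein Period and times larval development and molting, ranked 5 (II:1237909-1238264, intron, signal 113). That of pqn-41, a gene with a role in the death of the male linker cell, ranked 6 (III:1925160-1925515, intron, signal 98.8). The peak of bet-2, a bromodomain gene, ranked 7 (X:10568681-10569036, intergenic, summit at -414 bp from its transcription start site (TSS), signal 94.2). The lin-42, pqn-41 and bet-2 peaks ranked 5, 10 and 6 in the list of replicate 1, and 23, 6 and 14 in that of replicate 2.

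Further genes near the 20 strongest peaks included puf-9, myrf-1 and daf-16, while most nearest genes had only a sequence name. The peak of puf-9, a Pumilio-family RNA-binding protein gene, ranked 12 (X:5841115-5841470, signal 83.5), with its summit at -299 bp from the TSS and inside an exon of the non-coding RNA gene W06B11.7. The peak at -422 bp from the TSS of myrf-1, which encodes a membrane-bound transcription factor required for larval molting, ranked 13 (II:10502785-10503140, signal 82.1) and lay in an exon of the non-coding RNA gene F59B10.7. An intron of daf-16, the FOXO transcription factor gene of insulin signalling, held the peak of rank 16 (I:10769811-10770166, signal 76.7), with the non-coding RNA gene R13H8.5 as the nearest TSS. The peak of rank 15 lay in an intron of miz-1 (IV:10817073-10817428), that of rank 11 in an intron of ppfr-1 near F16A11.13 (I:9381220-9381575), and that of rank 8 in intergenic sequence at -3144 bp from egl-26 (II:66332-66687), a gene needed for vulval morphogenesis. The peaks of ranks 9, 10, 17, 18, 19 and 20 had F13D11.9, T19C3.11, the piRNA gene 21ur-13313, AH9.7, T14F9.7 and F13C5.2 as nearest genes. T14F9.19, within peb-1, was nearest to the peak of rank 14. In the list of replicate 2 the peaks of T19C3.11, T14F9.7 and F13C5.2 ranked 476, 1241 and 1523, against 8, 15 and 11 in that of replicate 1.

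Within 20 kb of peb-1 there were 8 thresholded peaks, where 10000 random windows of the same width held 0.0743 on average and 99.96% of them held fewer. All 8 fell between X:2208624 and X:2219351, with signals from 60.4 to 202. The excess extended to the relaxed lists, with 30000 candidate peaks each, that served as input to the reproducibility procedure. In the same window those lists held 42 peaks in replicate 1 and 45 in replicate 2, against random means of 14.3 in each and random maxima of 40 and 44. Outside the gene body, the 20-kb flanks alone held 31 and 35 peaks, against random means of 12 in each, 24 and 22 as the bounds exceeded by at most 0.5% of random windows, and random maxima of 38 and 45. Random windows were not kept away from peb-1, and the fullest held 9 thresholded peaks, a number that only windows over this locus can reach. The random maxima of the relaxed lists may therefore come from the same locus and do not show that other regions are as dense. The strain carries an integrated tagged transgene, per its name, so that the number of copies of this region in its genome is not known. At unc-119 (III:10902641-10908935), the gene whose mutation marks the parent strain, there were 0 thresholded peaks and 22 and 10 relaxed peaks, with 95.25% and 12.8% of random windows holding fewer.

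**Figure D1:**
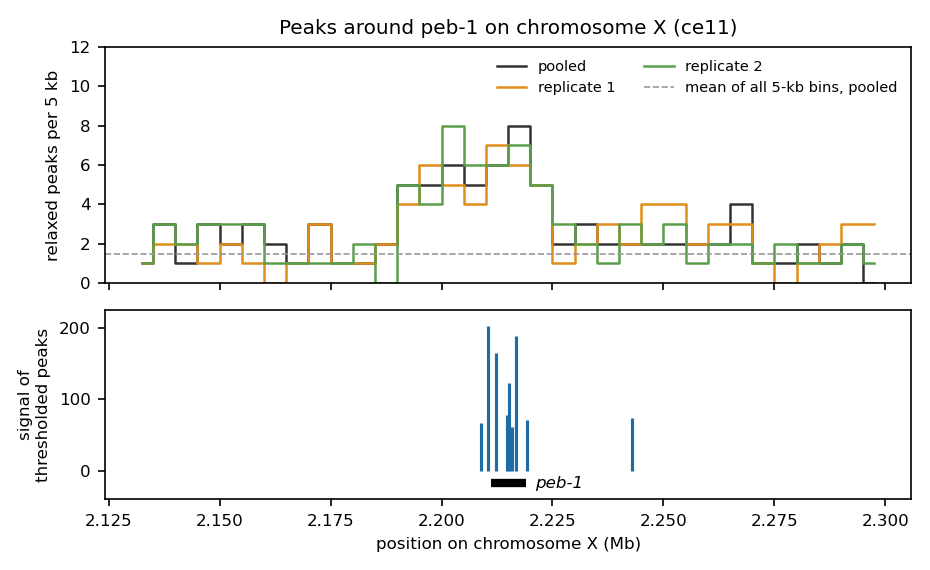
Peaks around peb-1 on chromosome X in ce11 coordinates. Top, number of relaxed-list peaks per 5 kb in the pooled list and in each replicate's list, with the genome mean of the pooled list (1.5) dashed; bottom, signal of each thresholded peak, with the peb-1 gene as a bar. The 7 bins from 2190001 to 2225000 each hold 5 to 8 pooled peaks.

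The X chromosome carried 61 of the 160 peaks (38.1%, interval 30.6-46.1), although it makes up 17.7% of the nuclear genome and 28.3 peaks would match its length. Chromosomes I, II, III, IV and V carried 17, 22, 22, 17 and 21 peaks. The distribution differed from chromosome length (chi-square statistic 49.0, Monte Carlo test with multinomial draws, p = 1e-05, the smallest that 100000 draws can give). X held 45% of the 160 highest-ranked peaks of replicate 1 and 28.8% of those of replicate 2. Without the 8 peaks at peb-1, an exclusion chosen after seeing the data, the X share was 34.9% (27.3-43). Among all 30000 pooled relaxed peaks it was 19.8%, and it was 32.5% for pooled ranks 161 to 320 and 24.4% for ranks 641 to 1000.

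**Figure D2:**
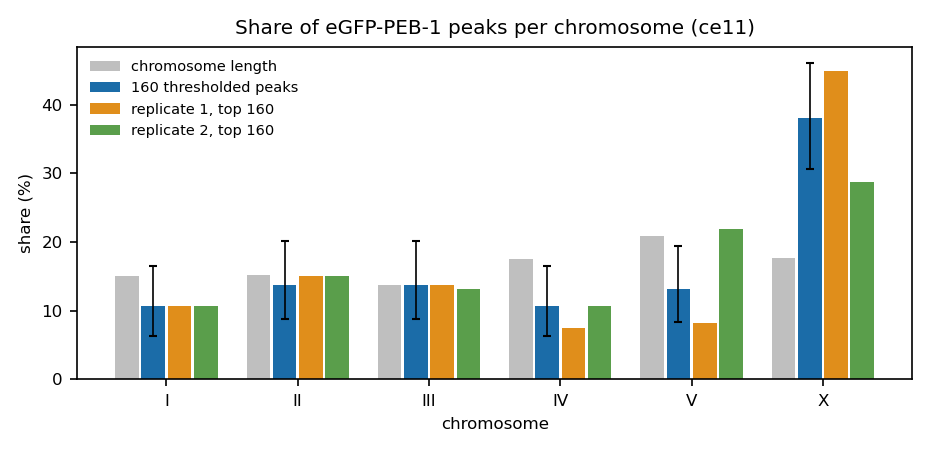
Share of peaks on each nuclear chromosome (percent), for chromosome length, the 160 thresholded peaks with exact 95% binomial intervals, and the 160 highest-ranked peaks of each replicate. Chromosome X holds 38.1% of the thresholded peaks, 45% and 28.8% of the replicates' highest-ranked peaks, and 17.7% of the length.

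Sites lay near gene starts and in non-coding RNA genes, and seldom in coding sequence. From 1000 bp upstream to 200 bp downstream of an annotated TSS lay 70% of the 160 summits (interval 62.3-77.0). Random placement on the same chromosomes gave 35.8% on average and 51.9% at most (two-sided permutation test by placement, p = 0.0002, the smallest that 10000 placements can give). For TSSs of protein-coding genes alone the share was 43.1% against 25.1%, and in pooled relaxed peaks outside the thresholded set the share near any TSS was 39.1% (Fisher's exact test, p = 5.58e-15). The median distance to the nearest protein-coding TSS was 1156 bp. Of the 160 summits, 83 were intergenic, 30 intronic, 5 in a coding exon, 5 in a 5′ UTR and 0 in a 3′ UTR, which allows a 3′ UTR share of up to 2.28%. Coding exons held 3.13% of summits against 23.6% of random placements (adjusted p = 0.0006, permutation test by placement with Benjamini-Hochberg adjustment over 6 classes), and introns 18.8% against 32.3% (adjusted p = 0.0012).

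Exons of non-coding RNA genes held 37 of the 160 summits (23.1%, interval 16.8-30.4), where random placement gave 1.6% and other pooled peaks gave 2.39%. Such summits can also count as near a TSS, so this share and the promoter share are not independent. Of these 37, 30 lay only in genes of the annotated class ncRNA, such as T14F9.17, F13D11.9, W06B11.7 and F59B10.7. Others lay in C52E4.8, an snRNA gene (summit V:11980246), and in F07A11.15, a snoRNA gene (summit II:11620133). Against pooled peaks matched on GC content, a background added after seeing the data, the share was 23.1% against 8.02% (Fisher's exact test, p = 3.98e-08). It was 21.9% for the highest-ranked peaks of replicate 1 and 10.6% for those of replicate 2, each above random placement (permutation by placement, p = 0.0002 for both, the smallest possible).

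Among 39 gene lists, 3 held more targets than other genes and 1 held fewer; a target had a thresholded summit in its promoter window. MicroRNA genes were targets in 9 of 261 cases (3.45%) against 0.418% of other genes (odds ratio 8.51, interval 4.31-16.8; Fisher's exact test with Benjamini-Hochberg adjustment, adjusted p = 4.26e-05). The 9 genes came from 6 peaks, and the strongest were those of mir-53 (rank 47, summit at -150 bp from the TSS), mir-241 (rank 50, -506 bp), mir-52 (rank 53, -188 bp) and lin-4 (rank 84, -398 bp). The genes mir-64, mir-65, mir-66 and mir-229 shared 1 peak (rank 111), which overlapped no peak of replicate 2, nor did that of mir-52. In replicate 2 the peaks of mir-241 and mir-1 ranked 15541 and 11717, and those of mir-53 and lin-4 ranked 396 and 39. Elsewhere in the promoter windows of mir-52 and mir-241, outside the thresholded peak, the best peaks of replicate 2 ranked 269 and 6299. Genes that share a peak are not independent in this test. Of snoRNA genes, which guide the modification of other RNAs, 10 were targets (2.89% against 0.417%, odds ratio 7.12, interval 3.73-13.6, exact test, adjusted p = 4.26e-05), among them F07A11.15, F54C9.12, C06A1.9 and smy-2. Of ribosomal protein genes 3 of 67 were targets (4.48% against 0.387%, odds ratio 12.1, interval 3.71-39.3, exact test, adjusted p = 0.0240): rpl-11.2 (rank 18, -377 bp), rps-18 (rank 57, -751 bp) and rpl-35 (rank 75, -429 bp). Of the 15363 piRNA genes, which form dense clusters, 5 were targets (0.0325% against 0.646%, exact test, adjusted p = 1.11e-26), among them 21ur-10927, 21ur-14806, 21ur-13302 and 21ur-14944. The test counts clustered piRNA genes as independent, and the 5 came from 4 peaks, so this p-value overstates the evidence for fewer targets. In the highest-ranked peaks of replicate 2 alone, microRNA, snoRNA and ribosomal protein genes no longer passed (0.766%, 0.867% and 2.99% targets; exact tests, adjusted p = 0.708, 0.467 and 0.165), and ribosomal protein genes did not pass in those of replicate 1 either (adjusted p = 0.173). The ribosomal call was also lost with the narrower and the wider promoter window (exact tests, adjusted p = 0.111 and 0.0532) and against genes with a pooled relaxed peak (adjusted p = 0.0525). With each peak given to the nearest TSS, microRNA genes (0.766% targets) and ribosomal protein genes (1.49%) did not pass (exact tests, adjusted p = 0.806 for both). Among the 80 peaks with the highest signal, microRNA and snoRNA genes did not pass (exact test, adjusted p = 0.163 and 0.185).

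The fixed heterochronic list held 21 genes that set the order of larval cell fates, of which the 15 protein-coding ones were tested. It did not pass with 1 target (6.67%, exact test, adjusted p = 0.253). That target was lin-14, a transcription factor gene silenced by the lin-4 microRNA, with a peak of rank 30 at X:11465209-11465564 (intergenic, summit at -173 bp from the TSS, signal 62.1). Its peak ranked 27 in replicate 1 and 988 in replicate 2. The peak of lin-4 (II:5901678-5902033, in an exon of the non-coding RNA gene F59G1.12 inside F59G1.4, signal 43.1) ranked 131 and 39, and that of mir-241, a member of the let-7 microRNA family (V:14366611-14366966, intergenic, signal 52.1), ranked 32 and 15541. With a window from 2000 bp upstream to 500 bp downstream the heterochronic list passed (13.3% of members, exact test, adjusted p = 0.0320), since lin-42 then counted as a target. With each peak given to the gene with the nearest TSS it passed as well (13.3%, exact test, adjusted p = 0.0201), as did the list of TGF-beta and insulin signalling genes (7.69%, adjusted p = 0.0363), while the microRNA and ribosomal protein lists lost their calls.

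None of the 4 lists of pharyngeal genes passed. None of 14 pharyngeal muscle genes, 11 pharyngeal gland genes or 16 pharyngeal cuticle genes was a target, nor was any of 176 collagen genes, and of 14 pharyngeal transcription factor genes the 1 target was peb-1 (7.14% against 0.396% of other genes, exact test, adjusted p = 0.253). The tests of lists this short leave wide limits, and with Fisher's exact test the adjusted p was 1 for each of the 4 lists without a target. No thresholded peak lay in the window of myo-2 (X:12468061-12475348), where the best pooled peak ranked 1032 and the best replicate peaks ranked 715 and 7507. The windows of ceh-22 and unc-119 held no pooled peak, and those of pha-4 and let-7 held pooled peaks of rank 9127 and 321. Of the other FLYWCH genes, flh-1 and flh-3 had no pooled peak in the window and flh-2 had 1 of rank 7212. In all, 22 of the 39 lists had no target and 35 did not pass, with 7 lists at an unadjusted p under 0.05.

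Remaining list members with a peak in the promoter window were spread over functions. They included the actin gene act-4 (rank 145), the Akt kinase gene akt-2 (rank 72, -780 bp, replicate ranks 127 and 101), the translation factor gene iff-2 (rank 62), the bZIP gene zip-2 (rank 80) and the helix-loop-helix gene hlh-11 (rank 135). The histone genes his-67 and his-68 shared 1 peak (rank 49). The tRNA genes C28G1.t1, F57F5.t1 and ZK994.t2, the snRNA genes C52E4.8 and sls-2.2 and the long non-coding RNA gene linc-78 were also targets. The act-4 and his-67 peaks ranked 68 and 40 in replicate 1 but 13764 and 7875 in replicate 2. None of the lists of body wall muscle, histone, translation factor, tRNA, snRNA or long non-coding RNA genes passed.

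Sequence at the summits held the recalled PEB-1 consensus YDTGCCRW more often than the flanks. It lay within 100 bp of 32 of 160 summits (20%, interval 14.1-27) and in 32 of 320 flanking windows 400 to 600 bp away (10%; odds ratio 2.25, interval 1.32-3.83; Fisher's exact test, two-sided, p = 0.00406). All tests against flanks treat a summit and its own flanks as independent windows. Of 100 other orders of the same letters, 14 had a higher odds ratio. Against pooled peaks matched on GC content the difference did not pass (14.7% in the background, exact test, p = 0.0827), nor within 200 bp against flanks (25.6% against 20.9%, p = 0.249). The core of the consensus, DTGCCR, was present at 65% of the 160 summits (interval 57.1-72.4) against 28.8% of flanks (odds ratio 4.60, p = 3.31e-14, Fisher's exact test). It also exceeded the GC-matched peaks (43.4%, odds ratio 2.43, interval 1.73-3.41, exact test, p = 1.81e-07), a comparison added after seeing the data. Other orders of the letters of the core were not tried, so whether the enrichment is particular to this order was not tested. DTGCCR was found at 63.8% of the highest-ranked peaks of replicate 1 and 48.8% of those of replicate 2, above the flanks in both (p = 6.57e-12 and 8.04e-05, Fisher's exact test). Within 50 bp the core stood at 75 summits (46.9%). The 41 bp centred on the bet-2 summit (X:10568839-10568879, intergenic) read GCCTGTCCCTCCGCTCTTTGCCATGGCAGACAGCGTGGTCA, and those at lin-42 (II:1238067-1238107, intron) read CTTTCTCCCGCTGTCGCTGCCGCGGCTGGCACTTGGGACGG.

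GA-rich sequence was also more frequent at the summits than in the flanks. GAGAGA, fixed as a control motif, lay within 100 bp of 92 of 160 summits (57.5%, interval 49.4-65.3) against 11.6% of flanks (odds ratio 10.3, interval 6.5-16.46; Fisher's exact test, p = 1.08e-25). At 55% and 32.5% of the highest-ranked peaks of replicates 1 and 2 it exceeded the flanks in each (Fisher's exact test, p = 1.32e-23 and 5.36e-07). Among all 2080 6-mers, 431 were enriched and 292 depleted against other pooled peaks (Fisher's exact test, Benjamini-Hochberg adjusted over all 6-mers), and GAGAGA came first (adjusted p = 7.72e-36), followed by AGAGAG, CGTCTC and CCTCTC. The summits were rich in GC, with a mean of 50.1% ± 6.18 (SD, n = 160 windows) against 37.6% ± 6.88 in other pooled peaks; the highest-ranked peaks of replicates 1 and 2 had means of 50.8% and 42.4%. With GC-matched background windows 93 6-mers were enriched, GAGAGA still first (57.5% against 25%, exact test, adjusted p = 5.60e-13). In the highest-ranked peaks of replicate 2 alone, 61 6-mers were enriched. Of the other control motifs, the PHA-4 motif TRTTKRY (43.8% against 46.9% of flanks, p = 0.560) and the E-box CACGTG (1.88% against 2.50%, p = 0.759) did not differ by Fisher's exact test, and the GATA motif HGATAR was less frequent (36.2% against 46.9%, p = 0.0315). Against GC-matched peaks TRTTKRY was more frequent (34% in the background, exact test, p = 0.0147), CACGTG less frequent (6.5%, p = 0.0143) and HGATAR did not pass (30.9%, p = 0.179).

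**Figure D3:**
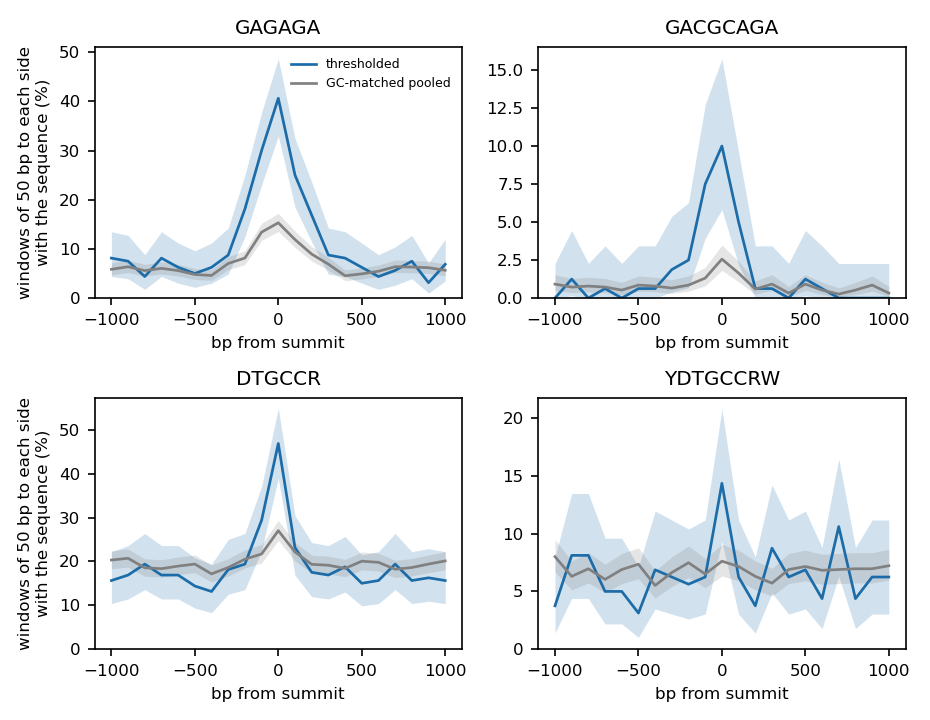
Percent of windows reaching 50 bp to each side that hold GAGAGA, GACGCAGA, DTGCCR or YDTGCCRW, by the distance of the window's centre from the summit (bp), for the 160 thresholded peaks and for GC-matched pooled peaks; bands are exact 95% binomial intervals. At the summit, DTGCCR is in 46.9% and YDTGCCRW in 14.4% of thresholded windows.

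The 8-mer with the lowest p-value was GACGCAGA, present at 29 of 160 summits (18.1%, interval 12.5-25) against 1.63% of other pooled peaks (adjusted p = 7.75e-17 over 32896 8-mers, Fisher's exact test with Benjamini-Hochberg adjustment). Against GC-matched peaks it was also first by p-value (4.47% in the background, exact test, adjusted p = 0.000116). It was present at 15.6% of the highest-ranked peaks of replicate 1 and at 6.25% of those of replicate 2. The peaks with this 8-mer included those nearest to pqn-41, egl-26, myrf-1 and miz-1. At pqn-41 the site stood at III:1925431-1925438 on the minus strand, in the sequence GAGAGACTGAGACGCAGAGAACACGACA. At myrf-1 it stood at II:10502903-10502910 on the minus strand, in CCGCCTCGGAGACGCAGACAGGTTGGCG. There were 32 sites in all, at a median distance of 46 bp from the summit. Sites were sought only within 100 bp, and 17 of the 32 lay within 50 bp, so this median alone does not show that they centre on the summit.

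**Figure D4:**
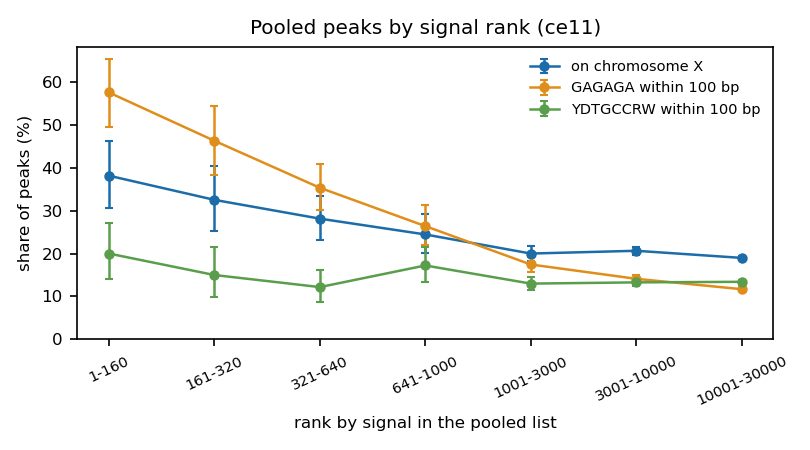
Percent of pooled ce11 peaks on chromosome X, with GAGAGA and with YDTGCCRW within 100 bp of the summit, by rank of signal; bars are exact 95% binomial intervals. From ranks 1-160 to ranks 10001-30000, GAGAGA goes from 57.5% to 11.7% and the X share from 38.1% to 19%.

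The replicates shared part of their strongest peaks, most closely at peb-1. Of the 8 thresholded peaks at peb-1, 7 ranked within the first 12 of replicate 2, and the peaks of pqn-41, egl-26 and F16A11.13 ranked 6, 8 and 7 there. Of the 160 highest-ranked peaks of replicate 1, 45 overlapped 1 of the 160 highest-ranked of replicate 2 (28.1%, interval 21.3-35.8). Random placement gave 0.229 on average and 3 at most (one-sided permutation p = 0.001, the smallest that 1000 placements can give). Every thresholded peak overlapped a peak in the relaxed list of replicate 1, at a median rank of 84.5, and 149 (93.1%) overlapped one in that of replicate 2, at a median rank of 484. In replicate 1 125 of them ranked within the highest 160 and in replicate 2 56 did, 44 in both. Since each relaxed list covered 10.7 Mb, overlap with it alone is weak evidence, and 90 of the 160 peaks (56.2%) ranked within the highest 1000 of both. Across the 128 of the 160 highest peaks of replicate 1 matched 1 to 1 to a peak of replicate 2, Spearman's rho of signal was 0.465, a value across peaks, which are not independent replicates. The highest signal was 154 in replicate 1 and 54.2 in replicate 2, on scales that the sources used here do not relate to each other.

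**Figure D5:**
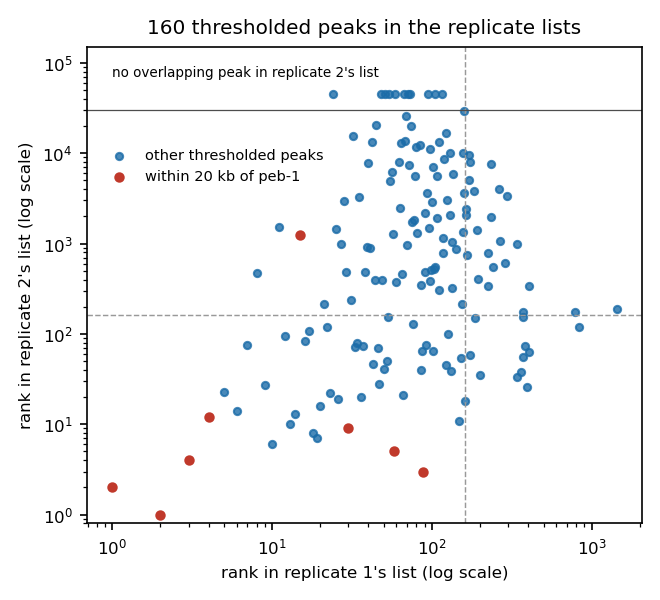
Rank of each of the 160 thresholded peaks in the list of replicate 1 and of replicate 2 (log scales). Dashed lines mark rank 160, red points lie within 20 kb of peb-1, and points above the solid line are the 11 peaks with no overlapping peak in replicate 2.

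The list in coordinates of the older ce10 build held 152 thresholded peaks, 62 of them on X (40.8%, interval 32.9-49.0). Chromosomes I to V held 15, 23, 18, 16 and 18. Its signal had a median of 44.4 and a maximum of 203, and 152 and 143 of its peaks overlapped a peak of replicates 1 and 2. Coordinates were not converted between builds, so single peaks were not matched.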

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

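Promoter share, the X excess, the overlap of replicates and the count of pooled peaks at peb-1 kept their direction and side of the threshold under every alternative run for them, with promoter shares from 43.1% to 81.9%, X shares from 28.8% to 47.5% and shared peaks from 19.1% to 35%. At unc-119 the pooled count stayed within the range of random windows, with 14 peaks against a mean of 13.9 for 20-kb flanks, 8 against 7.87 for 10 kb and 23 against 25.9 for 40 kb. Of all alternatives to the results that answer a comparison, 48 kept the call or a count within 1.5 times, 7 moved the value and 2 ended its call; of those for single lists, motifs and peaks, 450 kept it, 23 moved it, 16 ended a call and 5 gained one. The recalled motif YDTGCCRW lost its call within 200 bp of the summit (25.6%, p = 0.249) and against GC-matched peaks (20% against 14.7%, p = 0.0827, Fisher's exact test), and the cause was not tested. The number of enriched 6-mers fell from 431 to 93 against GC-matched background and ranged from 61 to 450 when either replicate was left out, of which the cause was not tested. The GC-matched background was also smaller, but 20 random backgrounds of the same 1522 windows, an alternative chosen after seeing the data, gave 383 to 412, so its size alone did not account for the fall. The number of lists with more targets than chance was 3, and a similar number did not mean the same lists. With the wider window heterochronic genes passed in place of ribosomal protein genes, with the nearest TSS heterochronic and TGF-beta and insulin genes passed beside snoRNA genes, and with the nearest protein-coding TSS, where lists by gene class were not tested, only heterochronic and TGF-beta and insulin genes passed. The number was 1 for the 80 peaks with the highest signal, 0 for peaks in the highest 1000 of both replicates, a set chosen after seeing the data, and 0 to 2 when either replicate was left out. Fewer peaks enter the first and second of these by construction, while the cause in the others was not tested. The stricter threshold kept 80 peaks by construction, and 76.9% of thresholded peaks had a summit within 100 bp in both replicate lists, against 93.1% by overlap, the looser rule. No paired analysis was possible because there was 1 group. Read depth, which limits how many sites a replicate can show, was not given in the sources used here.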

Other observations

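The tests of extra copies and of DTGCCR at peb-1, of the X share without that locus, of the octamer on X, of X against autosomal peaks, of GAGAGA in GC-matched peaks, in replicate 2 and without the locus, of heterochronic genes with microRNAs and of nearest protein-coding genes were chosen only after the results were seen, as were the genes named first here; the X share in each replicate was planned but set against an explanation only afterwards.

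Some further peaks, picked by their nearest gene and not tested as a set, lay at daf-12, din-1, myrf-2, blmp-1 and lin-14. An intron of daf-12, a nuclear receptor gene that controls dauer entry and larval timing, held the peak of rank 90 (X:10637402-10637757, 1672 bp downstream of the TSS, replicate ranks 99 and 504). A GACGCAGA site lay 1 bp from its summit (X:10637578-10637585, plus strand), in GAGTGGAAGAGACGCAGAGTGCAGCAAC. The peak of rank 38 lay at -55 bp from a TSS of din-1, a cofactor of DAF-12 (II:11619955-11620310, replicate ranks 25 and 1444). The peak of rank 31 lay at -249 bp from a TSS of myrf-2, the paralogue of myrf-1 (X:10194448-10194803, replicate ranks 33 and 71), and that of rank 141 in a coding exon of blmp-1, a transcription factor gene of larval timing (I:10409305-10409660, replicate ranks 141 and 861). A further peak of lin-14 ranked 44 in an intron (X:11474195-11474550, replicate ranks 28 and 2932).

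With microRNA members counted, 3 of 21 heterochronic genes were targets, namely lin-14, lin-4 and mir-241 (14.3%; odds ratio 38.7, interval 11.3-132; Fisher's exact test, p = 0.000102). With the window from 2000 bp upstream to 500 bp downstream there were 5 of 21, adding lin-42 and lep-5 (p = 2.87e-07, Fisher's exact test). In the highest-ranked peaks of replicate 2 alone there was 1 of 21, lin-4 (p = 0.0566, Fisher's exact test). With each peak given to its nearest protein-coding TSS, lin-42, lin-14 and daf-12 made up 20% of the heterochronic list (adjusted p = 0.00274, Fisher's exact test), and daf-16, sma-9, akt-2 and daf-12 made up 15.4% of the TGF-beta and insulin list (adjusted p = 0.00125). The gene daf-12 counted in both lists. Nearest-TSS rules count a peak at any distance, so genes with long introns or flanks are more likely to receive one, which the test does not allow for. X peaks and autosomal peaks did not differ past the threshold in any of 5 properties compared after the fact. The closest was GACGCAGA, at 8.20% of X and 24.2% of autosomal summits (Fisher's exact test, p = 0.0112, adjusted p = 0.0558).

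The 8 strong peaks at peb-1 sat in a wider block of relaxed peaks. If extra copies of the transgene raised read density over the block, all lists should hold an excess there, and the list with fewer peaks held 42 within 20 kb, above the 40 of the fullest random window for that list. That random window may itself overlap the locus. The count of 42 includes the strong peaks, but the flanks outside the gene body, with 3 of the 8, also held 31 and 35 relaxed peaks, above the 24 and 22 that at most 0.5% of random windows exceeded. Since the block was seen before these tests, they cannot separate extra copies from binding of PEB-1 at its own gene, and both stay open. The locus peaks held GAGAGA or GACGCAGA in 25% of cases against 63.2% of the other thresholded peaks (Fisher's exact test, p = 0.0562), and DTGCCR in 75% against 64.5%, not enriched past the threshold over the 50% of their own flanks (p = 0.388), so with 8 peaks it cannot be told whether the locus has the same class of sequence as other sites.

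The excess of peaks on X was set against 3 technical explanations and 1 of sequence. Without the peb-1 locus the X share was 34.9% (27.3-43), above the 17.7% of length, and the lower of the shares in the 2 replicates was 28.8% (21.9-36.4). The replicate shares still include the peaks at peb-1, most of which ranked near the top of replicate 2. Both exclusions were not combined, so an excess in replicate 2 outside the locus was not tested. GC content is argued against as the cause, since 19.1% of GC-matched pooled peaks were on X, below the interval of the thresholded share. Exact matches of the octamer GCGCAGGG, at 5 X summits and 0 of the 99 autosomal summits (Fisher's exact test, p = 0.00725), are too rare to account for an excess of 32.7 peaks. They were at 8.20% of thresholded X summits against 0.273% of other pooled X peaks (Fisher's exact test, p = 1.76e-06). Sequences that differ from the octamer were not counted, so a looser form of it stays open. Other technical causes, such as the distribution of the control reads, were not analysed here and stay open, and no biological explanation other than the octamer was tested.

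The GA-rich sequence at the summits was set against 4 technical explanations. GC-matched pooled peaks held GAGAGA in 25% of windows, below the 57.5% of the summits (odds ratio 4.07, interval 2.91-5.68; Fisher's exact test, p = 2.69e-16). Simple repeats were few, with a GA run of 12 bp or more at 5.43% of the summits with GAGAGA (5 of 92). Neither a single replicate nor the locus accounted for it, since the highest-ranked peaks of replicate 2 held it in 32.5% against 12.5% of flanks (p = 5.36e-07) and the peaks outside the peb-1 locus in 59.9% against 11.8% (p = 2.73e-26, Fisher's exact test for both). A candidate explanation is a GA-binding factor at open promoters that many tagged proteins reach, a hypothesis that 1 target protein and no comparison group could not test.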
